A study of Homo sapiens with 4 samples.

How the data were processed

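Gene expression was measured on 4 1-colour oligonucleotide arrays hybridised with biotin-labelled total RNA of MCF7 cells, 1 array for each of 4 groups. Per the labels' protocols, cells received mock siRNA or siRNA against PKCtheta at 20 nM for 48 h and were then left unstimulated or stimulated with PMA at 0.65 ng/ml for 60 h. The labels do not settle whether the unstimulated cells were harvested at 48 h or kept for the additional 60 h, so the PMA comparisons may also hold a difference in time after transfection. Groups were taken from the sample titles, and the labels state that there were no replicates.

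The deposited values are log2 expression values made by the authors with RMA (background correction, normalisation between arrays and summarisation of probes), per the submitters' processing notes. The software, its version and the settings are not given in the sources used here. The table holds 53617 probe sets, called probes below. Over all probes the array medians were 6.50 for mock unstimulated, 6.50 for mock with PMA, 6.52 for PKCtheta siRNA unstimulated and 6.52 for PKCtheta siRNA with PMA, and the sorted values of the arrays differed by up to 0.123. RMA assumes a similar distribution of values on each array, so a shift of most transcripts in 1 direction would not be seen. It also leaves residual background in dim probes, which shrinks their differences, and no detection call was used here. The number of arrays limits the precision.

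Probes were named through the platform annotation: 16098 probes had 1 gene symbol, 0 had several and 37519 had none in the annotation used here. All 16098 Entrez Gene identifiers matched the RefSeq gene table of assembly GRCh38.p14, which was used for names only, and 0 symbols needed updating. The genome build of the array design is not given in the sources used here, so no coordinates are printed. For the 779 genes with more than 1 probe, the probe with the highest mean over the 4 arrays was used. This left 14884 named genes, of which 11916 were protein-coding and 1072 were microRNA genes. Unnamed probes stayed out of the gene comparisons.

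Differences between single arrays were taken on the log2 scale. A gene was counted as higher or lower when the difference was at least 2-fold (a log2 difference of 1) and the brighter of the arrays compared reached the brightness floor, the median level of the named genes (7.31). For gene lists, all measured members count towards the median and the numbers 2-fold apart, with no floor, and the number that also meets the floor is given where it differs. These counts come from no test and carry no p-value. An upper bound on the array error was taken from the difference between the arms' PMA differences, which holds the error of all 4 arrays and any real difference. Its robust SD over 8123 genes was 0.288, which bounds the SD of a difference between 2 arrays at 0.203 if the error is alike for all genes.

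The test that the design allowed was an additive model with an siRNA term and a PMA term, fitted with limma 3.58.1 (R 4.3.3; lmFit and eBayes) to the 8123 named genes above the floor on at least 1 array, with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom, in which array error and any dependence of the PMA difference on the siRNA cannot be separated, so genes whose PMA difference depends on the siRNA rarely pass. On simulated data of 8123 genes, the PMA term was called for 86 of 100 genes with a true log2 change of 1, for 100 of 100 with a change of 2, for 0 of 7523 unchanged genes and for 1 of 200 genes altered by PMA in the mock arm only. The siRNA term was called for 80 of 100 and 100 of 100 genes and for 1 of 7523 unchanged genes. The simulated genes were more alike in error than limma's prior on the real arrays implies (2.69 degrees of freedom). These rates may thus be too high for the real arrays. There, ERP27, higher with the siRNA by 1.91 without PMA and by 2.02 with PMA, was not called by the siRNA term. The words rose and fell are used for genes that passed this test, and higher and lower describe the other differences.

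A total of 34 gene lists, 711 genes in all, were written before the data were examined, and 31 of them had a measured member. The lists of integrins, replication-dependent histones and mitochondrial transcripts had 0 measured members and are not analysed here. For each list, the median log2 difference over all measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. This percentile describes these arrays and is not a p-value. In a check on simulated data, 20 of 20 shifted random lists lay above the 97.5th percentile, and 3 of 20 unshifted lists lay outside the central 95%. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 were used.

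Named genes followed a rule written before the data were examined. PRKCQ, CDH1, VIM, CD44, CD24, PLAUR and ESR1 were to be named in any case. Added to these were the 12 genes with the highest and the 12 with the lowest mean PMA difference among genes at least 2-fold apart the same way in both arms, and the 6 highest and 6 lowest for siRNA among genes at least 1.5-fold apart in both PMA states. The 10 highest and 10 lowest differences between the arms' PMA differences and up to 4 members of each list per comparison completed the rule. MicroRNA, small nucleolar and unnamed transcripts were left out of the ranked parts. Genes for the ratio of PMA differences between arms were chosen by the mean of both arms, and with either arm alone for comparison. Alternatives were no floor, a floor at the 75th percentile, cyclic loess or quantile normalisation of the deposited values, the mean of a gene's probes, a 1.5-fold threshold, a limma prior with trend and robust fitting, and a model without the other factor. Leaving out a replicate was not possible with 1 array per group.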

Results

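The series addressed the role of protein kinase C theta (PKCtheta, the product of PRKCQ) in epithelial to mesenchymal transition. RNA was taken from MCF7, a human breast cancer line of luminal, estrogen receptor-positive type. Cells carried mock siRNA or PKCtheta siRNA and were left unstimulated or treated with PMA, a phorbol ester that activates protein kinase C. Each of the 4 groups had 1 array, so the values below are single measurements or differences between single arrays, given on the log2 scale unless called a fold, and have no SD. Over all probes, Pearson's r between arrays ranged from 0.976 (mock with PMA against PKCtheta siRNA unstimulated) to 0.988 (the PKCtheta siRNA arrays without and with PMA).

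The siRNA target could not be checked, because PRKCQ had no named probe in the annotation used here. CDH1, which encodes E-cadherin, and PLAUR, the urokinase receptor, had none either. Of the protein kinase C list, 3 of 12 members were measured, the protein kinase D genes PRKD1, PRKD2 and PRKD3. Their median PMA difference was 0.51 in mock cells and 0.10 in PKCtheta siRNA cells, with none 2-fold apart, and their median siRNA difference was −0.05 without PMA and −0.15 with PMA.

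In mock cells, PMA was compared with no stimulation; the PMA arrays may also differ in time after transfection, which the labels leave open. Interferon-response genes, which encode antiviral effectors, were higher with PMA, and genes of mitosis and DNA replication were lower. Of 28 measured interferon genes, 26 were at least 2-fold higher and 0 lower, with a median difference of 2.22. IFI44 was 29.5-fold higher, IFI44L 27.8-fold, IFIT3 24.3-fold and CXCL10, a chemokine, 21.2-fold, from unstimulated levels of 4.25 to 6.02. These lie below the brightness floor of 7.31, so the folds and their order are approximate. Of 5 leukocyte markers, CD68 was 2.63-fold higher and the others were less than 2-fold apart (median 0.19, or 1.03 over the 2 above the floor). Of 28 mitosis genes, 27 were at least 2-fold lower and 0 higher, with a median of −2.08. TOP2A, a DNA topoisomerase, differed by −2.83, and the mitotic kinesins KIF20A and KIF11 by −2.67 and −2.63. Of 23 DNA replication genes, 21 were at least 2-fold lower and 0 higher (median −1.52), among them TYMS (thymidylate synthase, −2.32), E2F8 (−2.29) and the GINS complex genes GINS1 (−2.21) and GINS2 (−2.14). Of the growth arrest list, 4 of 16 members were measured, and 0 were 2-fold apart (median 0.19).

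Lists of growth factor, MAP kinase and NF-kB signalling had positive medians with PMA in mock cells, and part of their members were at least 2-fold higher. Of 19 immediate early and AP-1 genes, 8 were at least 2-fold higher (median 0.80). The transcription factor EGR1 was 23.0-fold higher on its brighter probe and 0.59 higher on its dimmer probe, FOSL1 was 3.72-fold higher and JUNB 3.71-fold. With the mean of their probes, FOS (0.72) and IER3 (0.74), also a MAP kinase feedback gene, were less than 2-fold higher. Of 16 MAP kinase feedback genes, 8 were at least 2-fold higher (median 0.93), led by the phosphatases DUSP4 (5.91-fold), DUSP10 (5.09-fold) and DUSP5 (5.05-fold on its brighter probe, but a difference of −0.10 on its dimmer probe). The dimmer probes of EGR1 and DUSP5 were below the brightness floor on all arrays, where differences shrink. Of 11 EGF receptor ligands and receptors, 2 were at least 2-fold higher (median 0.36): the feedback inhibitor ERRFI1, with a difference of 2.70, and EGFR, 2.53-fold. Of 18 NF-kB targets, 4 were at least 2-fold higher (median 0.48), the chemokines CCL5 (6.98-fold) and CCL2 (2.99-fold), the adhesion molecule ICAM1 (3.31-fold) and NFKB2 (2.78-fold); CCL2 stayed below the brightness floor, which left 3. None of these 4 lists had a member 2-fold lower. Over members above the floor, the 4 medians were 0.83 (18 genes), 1.32 (11), 1.34 (3) and 0.63 (12).

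Invasion proteases and their inhibitors were at least 2-fold higher with PMA for 6 of 18 members, 5 of them above the floor, and lower for 0 (median 0.59, or 0.87 over the 11 above the floor). The collagenases MMP1 and MMP13 were 21.4-fold and 18.5-fold higher, from unstimulated levels of 5.07 and 4.63, below the brightness floor of 7.31. The protease inhibitors TIMP1 and TIMP2 were 2.70-fold and 2.58-fold higher. Of 14 actin cytoskeleton and YAP targets, 2 were at least 2-fold higher (median 0.22), ANKRD1 by 2.52-fold and ZYX, a focal adhesion protein, by 2.01-fold. Outside these lists, CEACAM6, a cell adhesion glycoprotein, was 16.8-fold higher.

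With PMA in mock cells, the epithelial list had a median of −0.06 over 28 genes, all above the floor, at the 40.4th percentile of matched random lists. The mesenchymal list had a median of −0.03 over 15 genes (49.4th percentile), but 13 of them were below the floor, and the other 2, FN1 and LOXL2, were both higher. CLDN1, a tight junction claudin, was the 1 epithelial member at least 2-fold apart, and it was higher (7.88-fold). No mesenchymal member was 2-fold apart; LOXL2, a collagen cross-linking enzyme, was 1.88-fold and fibronectin (FN1) 1.51-fold higher. VIM, which encodes vimentin, differed by −0.26 on its brightest probe and by 0.08 and 0.22 on its other probes. All its probes were below the floor on both mock arrays. Of 15 transcription factors of epithelial to mesenchymal transition, SOX4 was 2.70-fold higher and the others were less than 2-fold apart (median −0.01, or 0.31 over the 6 above the floor). SNAI2 was 1.67-fold higher from a level of 6.63, below the floor. Of 12 breast stem cell markers, CD44, a hyaluronan receptor, was 3.40-fold higher and the others were less than 2-fold apart (median −0.03, or 0.56 over the 5 above the floor). CD24 was 1.88-fold higher. Of 10 basal epithelial markers, EGFR was the 1 member 2-fold apart (median −0.07, or 0.05 over the 5 above the floor).

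The luminal and estrogen receptor lists had negative medians with PMA in mock cells. Of 20 luminal identity genes, 6 were at least 2-fold lower and 0 higher (median −0.36). AGR3 was 6.95-fold lower, the transcription factor MYB 3.58-fold, AGR2 2.92-fold and the progesterone receptor gene PGR 2.82-fold. ESR1, the estrogen receptor gene, was 2.74-fold lower. Of 26 estrogen receptor targets, 7 were at least 2-fold lower and 1, FHL2, was higher (2.74-fold), with a median of −0.48. ELOVL2, a fatty acid elongase, was 5.81-fold lower. Other genes lower with PMA in both arms included PEG10, a retrotransposon-derived imprinted gene, 9.22-fold lower in mock cells, and GFRA1, a GDNF family receptor, 3.43-fold lower. Over all 7882 named genes above the floor, 310 were at least 2-fold higher and 307 lower.

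In PKCtheta siRNA cells, the PMA differences were fewer. Over 7684 genes, 61 were at least 2-fold higher and 14 lower. Of the 28 interferon genes, 20 were at least 2-fold higher, 19 of them above the floor, and 0 lower, with a median of 1.76. IFIT1 was 23.3-fold higher, IFIT3 19.7-fold, DDX60, a helicase of antiviral sensing, 15.8-fold and IFIT2 10.7-fold, each from an unstimulated level below the floor. KIF20A (−1.11) was the 1 mitosis gene at least 2-fold lower, and the list had a median of −0.67. No replication gene was 2-fold lower (median −0.27). Luminal identity genes had a median of −0.26, with PGR (−1.53) and AGR3 (−1.46) at least 2-fold lower. Estrogen receptor targets had a median of −0.39, with PGR the 1 member 2-fold lower.

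The signalling and protease lists had few members past 2-fold in PKCtheta siRNA cells. With PMA, EGR1 (1.95, with −0.02 on its dimmer probe) was the 1 of 19 immediate early genes at least 2-fold higher, and the list's median was 0.14. With the mean of its probes, which includes the dimmer probe below the floor, EGR1 was at 0.97, and the list had 0 members past 2-fold. DUSP4 (1.23) and DUSP10 (1.14) were the 2 of 16 MAP kinase feedback genes (median 0.31, or 0.48 over the 9 above the floor). CCL5 (2.29) was the 1 of 18 NF-kB targets (median 0.05, or 0.22 over the 10 above the floor). Among the 18 proteases and inhibitors, MMP1 (1.33), MMP13 (1.27) and TIMP1 (1.20) were at least 2-fold higher, with a median of 0.05 (0.43 over the 9 above the floor). MMP1 and MMP13 stayed below the floor on both arrays, which left TIMP1 as the 1 member counted above it. EGF receptor ligands and receptors (median 0.09) and actin and YAP targets (median −0.09) had 0 members past 2-fold. Over members above the floor, these medians were 0.34 (2 genes) and −0.13 (11). CLDN1 was higher by 1.70, while the epithelial and mesenchymal medians were 0.05 and −0.03, with 3 of 15 mesenchymal genes above the floor. CD44 differed by −0.17 with PMA, SOX4 by 0.69 and ESR1 by −0.76.

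**Figure D1:**
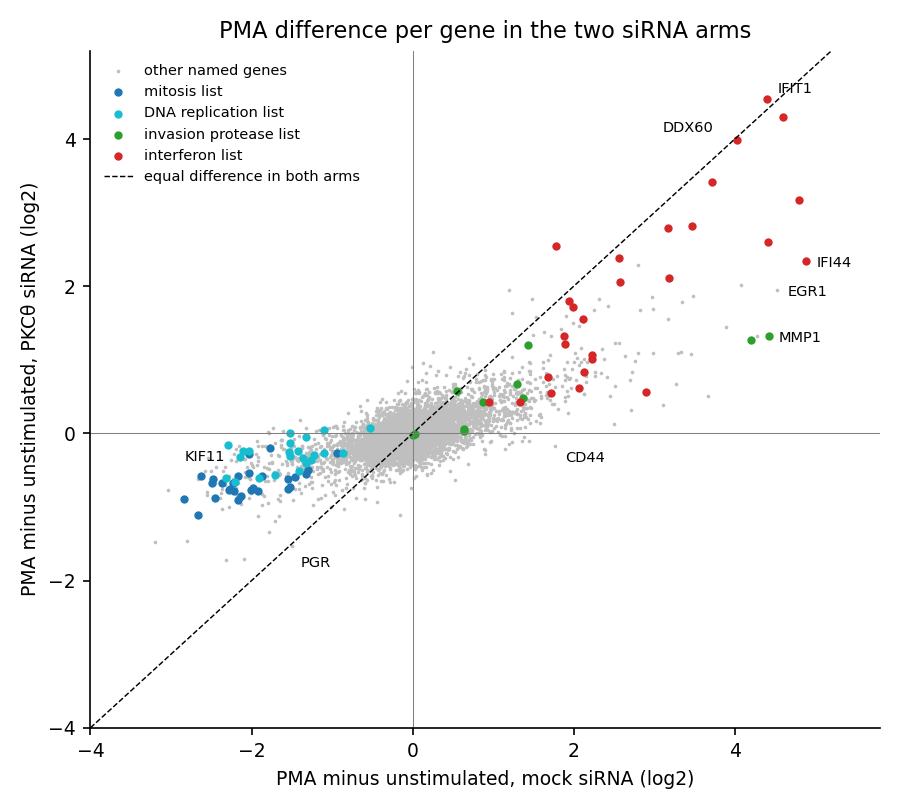
Log2 difference of the PMA array from the unstimulated array for each named gene above the brightness floor, in mock siRNA cells (x axis) and PKCθ siRNA cells (y axis), with members of 4 gene lists coloured and the line of equal differences dashed. Mitosis genes, with medians of −2.08 and −0.67, and the proteases MMP1 and MMP13 lie between the dashed line and the x axis, and IFIT1 and DDX60 lie close to the dashed line.

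Both arms placed many of the same genes past the threshold, although they share no array. With PMA, 59 genes were at least 2-fold higher and 12 lower in both arms, where independent lists of these sizes would share 2.54 and 0.577 genes. A further 2 higher and 2 lower genes passed in the siRNA arm but not in mock cells, and 0 genes passed in opposite directions. Across genes, which are not independent replicates, the PMA differences of the arms correlated with a Pearson's r of 0.726 and a Spearman's rho of 0.578.

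In the additive model over all 4 arrays, the PMA term passed for 4 of 8123 genes, all of the interferon list. IFIT1 (Entrez Gene 3434) rose with PMA by 4.47 (SE 0.11, limma adjusted p = 0.0274), IFIT3 (3437) by 4.45 (SE 0.13, adjusted p = 0.0274), DDX60 (55601) by 4.01 (SE 0.11, adjusted p = 0.0274) and IFIT2 (3433) by 3.57 (SE 0.13, adjusted p = 0.0438). Each was higher in both arms. At an unadjusted p below 0.05, limma's PMA term held 1198 genes, 618 of them higher. Without the siRNA term, 0 genes passed and 848 had an unadjusted p below 0.05. The siRNA term passed for 0 genes (smallest limma adjusted p = 0.298), and 1146 had an unadjusted p below 0.05. The unadjusted counts include genes that pass by chance and are not counts of changed genes.

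**Figure D2:**
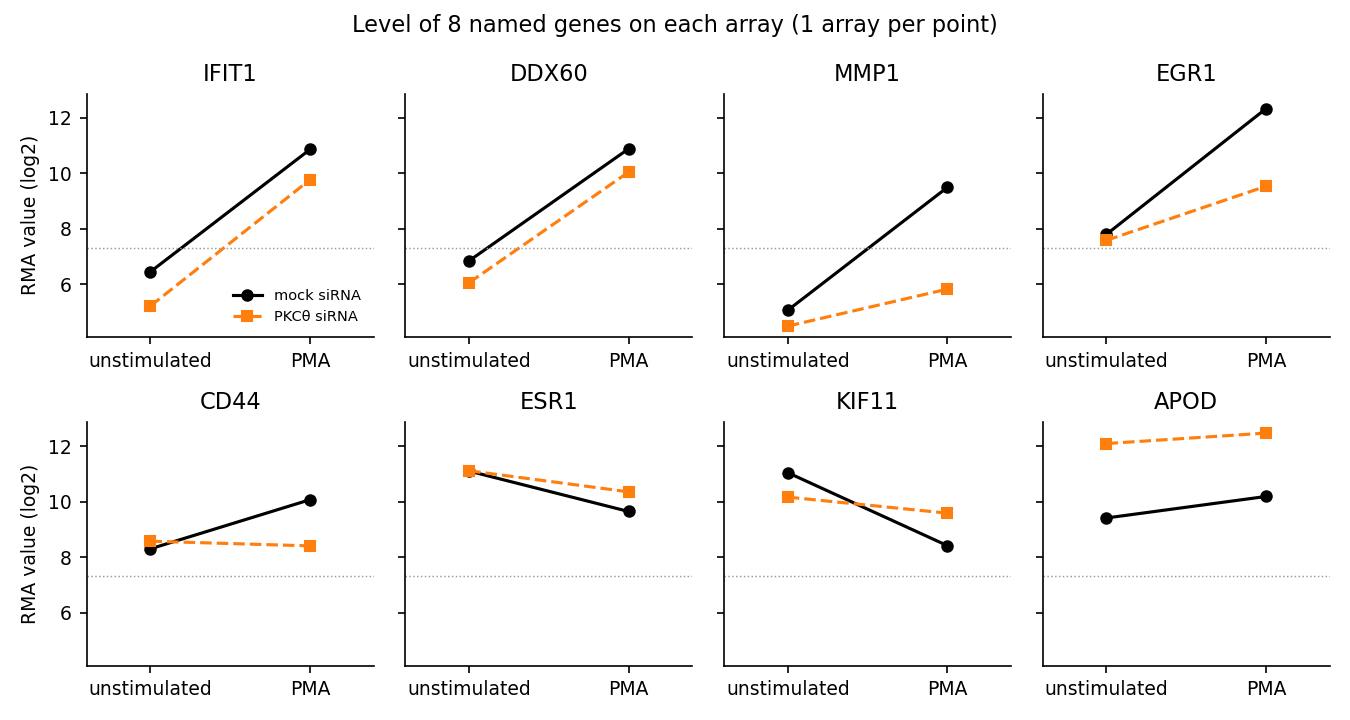
RMA level (log2) of 8 named genes on each of the 4 arrays, without and with PMA (x axis), in mock siRNA cells (black circles) and PKCθ siRNA cells (orange squares), with 1 array per point and the brightness floor of 7.31 dotted. IFIT1 and DDX60 were higher with PMA by similar amounts in both arms, CD44 differed by 1.77 in mock cells and −0.17 in PKCθ siRNA cells, and APOD was higher with PKCθ siRNA on both arrays.

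Without PMA, PKCtheta siRNA was compared with mock siRNA. Replication genes were lower with the siRNA, with a median of −0.64 over 23 genes, and CDC6 (−1.66) and MCM10 (−1.03), which license and start replication origins, were at least 2-fold lower. Mitosis genes had a median of −0.56 over 28 genes, with 0 members past 2-fold. Both medians lay at the 0th percentile of matched random lists. Of the interferon list, 5 of 28 members were at least 2-fold lower and 0 higher (median −0.29), led by IFIT3 (−1.86), IFIT2 (−1.56), IFIT1 (−1.23) and BST2 (−1.08). IFIT3, IFIT2 and IFIT1 were below the floor on both unstimulated arrays, which left 2 of the 5, BST2 and IRF9 (−1.04), above it. Of the luminal list, TFF1, an estrogen-regulated secreted peptide (−1.54), the apoptosis inhibitor BCL2 (−1.18) and the transcription factor XBP1 (−1.04) were at least 2-fold lower among 20 genes (median −0.28). TFF1 was also the 1 of 26 estrogen receptor targets past 2-fold (median −0.26).

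Among single genes, APOD, a lipid-binding lipocalin, was 6.40-fold higher with the siRNA in unstimulated cells and 4.86-fold higher with PMA. MINAR2 was higher by 1.88 and 3.46. ERP27, a protein of the endoplasmic reticulum, was 3.77-fold and 4.05-fold higher, and the ephrin receptor gene EPHA3 2.15-fold and 4.15-fold. CATSPERB was higher by 1.63 and 1.84, and the antisense transcript SYNPR-AS1 by 1.91 and 2.39. All of these except APOD were below the brightness floor on both mock arrays, so their sizes and order are approximate. SYNPO2, an actin-binding protein, differed by −1.57 and −1.45, PLEK2 by −1.11 and −1.89, and TFF1 by −1.54 and −1.27. SYNPO2 was below the floor on both PKCtheta siRNA arrays. In unstimulated cells, CD44 differed by 0.27, CD24 by 0.20, VIM by 0.24 and ESR1 by 0.01. The dimmer VIM probes, below the floor, differed by 0.25 and 0.71. The medians were −0.09 for epithelial, −0.05 for mesenchymal and −0.05 for transition factor genes, with 0 members past 2-fold; over members above the floor they were −0.09 (28), −0.42 (3) and −0.15 (5). Immediate early genes (−0.10), MAP kinase feedback genes (−0.17), NF-kB targets (−0.05) and proteases (−0.06) also had 0 members past 2-fold. Over 7728 genes, 25 were at least 2-fold higher and 37 lower.

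With PMA, PKCtheta siRNA was again compared with mock siRNA, and more genes passed 2-fold, 91 higher and 166 lower of 7778. MMP1 differed by −3.66 with the siRNA, MMP13 by −2.65, TIMP1 by −1.05 and MMP10 by −1.09. Of the 18 proteases and inhibitors, 5 were at least 2-fold lower, 4 of them above the floor, which MMP10 did not reach. MMP1 and MMP13 reached it on the mock PMA array only, so their sizes are approximate. The list's median was −0.24, or −0.49 over the 11 above the floor. Of 28 interferon genes, 18 were at least 2-fold lower and 0 higher (median −1.15), with IFI44 at −2.84, IFI44L at −2.32, IFIT3 at −2.17 and RSAD2 at −1.87. IFI44 and RSAD2 were below the floor on the siRNA array with PMA. EGR1 (−2.79, with −0.52 on its dimmer probe) and FOSL1 (−1.78) were among 4 of 19 immediate early genes at least 2-fold lower (median −0.68). DUSP4 (−1.95) and DUSP5 (−1.66, with −0.32 on its dimmer probe) were among 4 of 16 MAP kinase feedback genes (median −0.76). With the mean of their probes, DUSP5 (−0.99) and IER3 (−0.59), a member of both lists, were less than 2-fold lower. ICAM1 (−1.29) and NFKB2 (−1.20) were the 2 of 18 NF-kB targets at least 2-fold lower (median −0.53), and ANKRD1 (−1.77) was the 1 of 14 actin and YAP targets (median −0.47).

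In the same comparison, mitosis genes were higher with the siRNA by a median of 0.75, and 8 of 28 were at least 2-fold higher, with CDK1 at 1.21 and KIF11 at 1.17. Replication genes had a median of 0.50, with E2F8 (1.49) and PCNA (1.11) at least 2-fold higher among 23. CD44 was 3.16-fold lower with the siRNA. The 1 epithelial gene past 2-fold was CLDN1 (−1.32), with a median of −0.15 over the list, and the 1 mesenchymal gene was FN1 (−1.01). The epithelial median, though small, lay at the 0.59th percentile of matched random lists. The mesenchymal median was −0.09 over 15 genes (10.2th percentile) and −0.91 over the 3 above the floor. Of the 15 transition factors 0 passed 2-fold (median −0.15, at the 2.22nd percentile, or −0.41 over the 5 above the floor). LEF1, below the floor on both arrays, had the lowest value, −0.87, and SOX4 (−0.63) the lowest of the 5 above the floor. ESR1 differed by 0.71, CD24 by −0.37 and VIM by 0.29, with 0.09 and 0.33 on its dimmer probes, below the floor. AGR3 (1.66, below the floor on both arrays) was higher and TFF1 (−1.27) lower among luminal genes (median −0.17), and ELOVL2 (2.51) was higher and TFF1 lower among estrogen receptor targets (median −0.16).

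**Figure D3:**
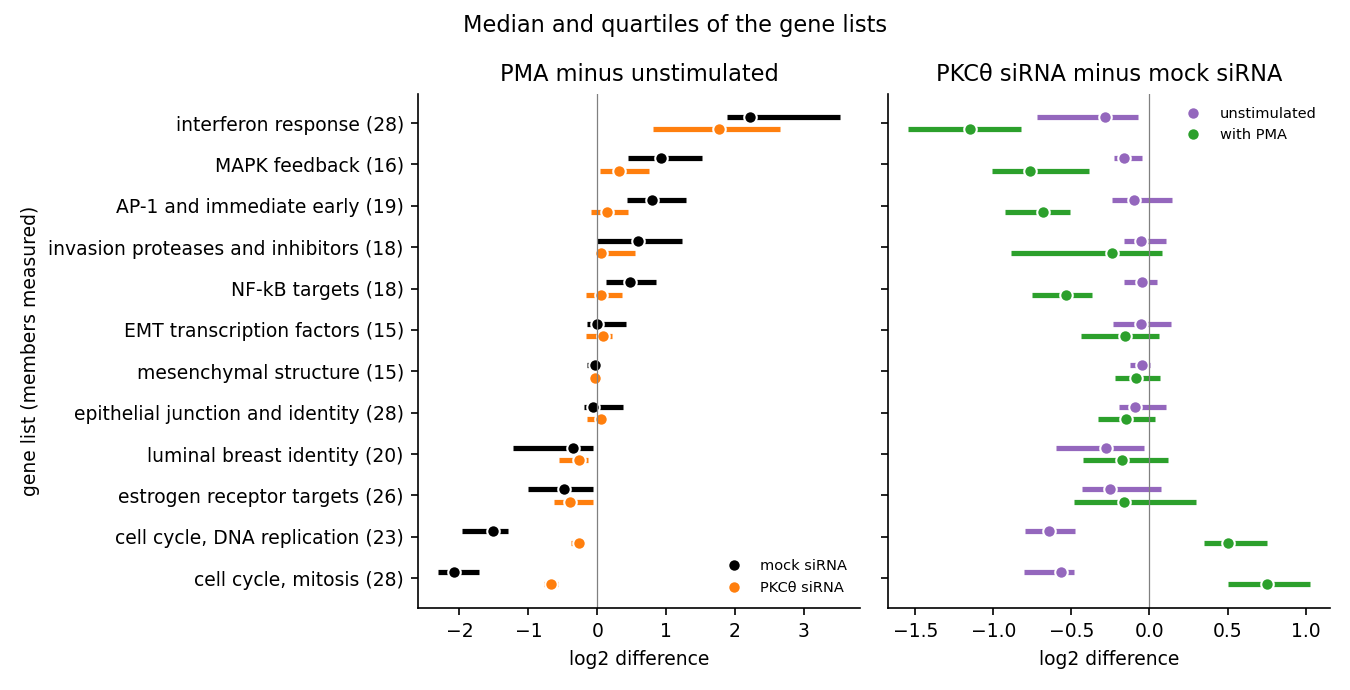
Median (point) and quartiles (bar) of the log2 difference over the measured members of 12 gene lists, for PMA against unstimulated in each siRNA arm (left) and for PKCθ siRNA against mock siRNA without and with PMA (right), from 1 array per group. The mitosis median is −2.08 and −0.67 on the left and −0.56 and 0.75 on the right, while the mesenchymal medians lie between −0.09 and −0.03, with at least 12 of the 15 genes below the brightness floor.

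The PMA differences of the arms were then set against each other. Among 148 genes whose mean PMA difference over both arms was at least 2-fold higher, the median difference was 1.99 in mock cells and 0.94 in PKCtheta siRNA cells, and 142 had the larger value in mock cells. The median ratio of the siRNA arm to the mock arm was 0.461 (quartiles 0.340 and 0.631). Among 140 genes at least 2-fold lower, the medians were −2.00 and −0.61, 139 had the larger size in mock cells, and the median ratio was 0.318 (quartiles 0.229 and 0.416). When the genes were chosen in the siRNA arm alone, which favours that arm, the ratios were 0.662 over 67 higher genes and 0.686 over 14 lower genes. When they were chosen in the mock arm alone, which favours the mock arm, the ratios were 0.364 and 0.274.

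Genes with the lowest difference between PMA differences (siRNA arm minus mock arm) were CEMIP, a hyaluronan-degrading protein (−3.16), MMP1 (−3.09), ARL14, a small GTPase (−2.95), and MMP13 (−2.94). TMEM156 (−2.73), CEACAM5, a cell adhesion glycoprotein (−2.60), EGR1 (−2.58, or −1.59 with the mean of its probes), IFI44 (−2.54), FBXO32, a ubiquitin ligase subunit (−2.45), and ceruloplasmin (CP, −2.39) followed. Among these, CEMIP, MMP1, ARL14, MMP13, TMEM156, IFI44 and CP were above the brightness floor on the mock PMA array only. Their values and order are therefore approximate. CD44 had a value of −1.93. The highest values were those of CABCOCO1 (2.26), ELOVL2 (2.21) and the cell cycle genes E2F8 (2.13), PLK4 (2.07), KIF11 (2.05), KIF15 (2.04), SMC2 (1.99), TICRR (1.99), DSCC1 (1.99) and CENPK (1.98). By list, 21 of 28 mitosis genes and 16 of 23 replication genes had values of at least 1, with medians of 1.46 and 1.22. Of 28 interferon genes, 10 had values of −1 or below (median −0.61), while IFIT1 (0.14) and DDX60 (−0.05) lay near 0. Over 8123 genes, 194 had values of at least 1 and 149 of −1 or below. With 1 array per group this difference could not be tested.

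A total of 138 genes were at least 2-fold higher with PMA in mock cells and at least 2-fold lower with PKCtheta siRNA under PMA, and 52 genes were lower and then higher. These comparisons share the mock PMA array. Independent lists of these sizes would share 6.74 and 3.66 genes, a value that leaves out the shared array. The highest count over 100 simulated sets of unchanged arrays was 0, which the threshold fixes at the estimated error, so neither value measures what the shared array adds. In the mirrored sets, which share the PKCtheta siRNA array with PMA, 2 genes were higher and 0 lower in both comparisons. These sets start from the 61 higher and 14 lower genes of the siRNA arm, against 310 and 307 in mock cells. Small mirrored counts thus follow in part from list size. Part of the overlap may come from the shared array, since each group had 1 array and the controls could not be split.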

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

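The tests in this part of the array scale, of a common factor, of starting levels, of leukocyte markers and of harvest time were chosen after the results were seen.

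Probes without a gene name were outside the gene comparisons above. In mock cells, 320 of 10555 such probes above the brightness floor were at least 2-fold higher with PMA than on the unstimulated array and 232 were lower. In PKCtheta siRNA cells the counts were 74 and 27 of 10442. Which transcripts these probes measure was not analysed here. A test for outlying samples within a group was not possible with 1 array per group.

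PMA differences were smaller in PKCtheta siRNA cells, with median ratios of 0.461 for higher and 0.318 for lower genes. A lower start of cell cycle genes that ended at a common level is argued against by a median difference of 0.75 between the PMA arrays over the mitosis genes. A common factor for all PMA genes, such as a smaller responding share of cells, could not be decided. The linear response share of the interferon genes had a median of 0.556 over 25 genes, against 0.273 over 123 other PMA-raised genes. It lay at the 100th percentile of random draws, although its quartiles were wide (0.279 and 0.802). The lowered mitosis genes had a close median share of 0.527 over 24 genes (quartiles 0.455 and 0.563). The quartiles of the other PMA-raised genes were 0.178 and 0.396. The lowered replication genes had a median share of 0.344 over 8 genes (quartiles 0.198 and 0.465). That median lay at the 1.98th percentile of random draws of lowered genes. However, the share takes each arm's fold over its own unstimulated array. The interferon list started lower in PKCtheta siRNA cells (median −0.29 without PMA), which can raise its share. The mitosis and replication lists also started lower, with medians of −0.56 and −0.64. Their unlike shares from similar starts go against 1 common factor, but on 8 replication genes with overlapping quartiles. One compression factor for the scale of the PKCtheta siRNA array with PMA is argued against by the lowered genes, which compression would pull down. Their median difference between the PMA arrays (siRNA minus mock) was 0.784. The raised genes do not decide it. The median log2 ratio of the interferon genes (0.701, against 0.430 for the other raised genes) lay at the 99.99th percentile of random draws. This ratio also depends on the lower start. A common factor for all PMA genes thus stays open, as does a compression among raised genes, including one that grows with brightness. A lower effective PMA dose to which genes differ in sensitivity and off-target effects of the siRNA stay open as untested. So does loss of PKCtheta itself, since PRKCQ had no named probe.

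Interferon-response genes were higher with PMA in both arms and held all 4 genes that passed the additive test. The RNA was of MCF7 cells, a breast cancer line, so the design holds no source of leukocyte RNA. The markers could not test for it, because only 2 of 5 leukocyte markers were above the brightness floor in mock cells. The median PMA difference of all 5 in mock cells, the higher of the arms, was 0.193, or 1.03 over the 2 above the floor. CD68, also a lysosomal gene of other cells, was at 1.39 there but at 0.08 in PKCtheta siRNA cells. This goes against leukocyte RNA, but on a single marker near the floor. Transcription of an interferon gene at harvest could not be decided, because 0 type I or III interferon genes had a named probe. A longer time since transfection in the PMA arrays cannot be told apart from PMA, because 0 unstimulated arrays were labelled with the later time. An action of PMA on these genes stays open as well.

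The 190 genes that were apart with PMA in mock cells and apart in the opposite direction with PKCtheta siRNA under PMA share the mock PMA array. Array error of that array cannot be told apart from a difference between the groups. The highest count over simulated unchanged arrays was 0. The simulated error SD of 0.203 for a difference, which assumes an error alike for all genes, fixes that outcome against a threshold of 1. The simulation thus excludes nothing, and no further mock PMA array was analysed here. A biological difference stays open as untested.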

How the results depend on the processing

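Of 85 alternative values of counts, tests and ratios, 66 stayed within the limits set, 19 moved and 0 reversed. Cyclic loess and quantile normalisation moved none of them. The deposited values were already normalised, with sorted values up to 0.123 apart, so these settings left little to change and do not show independence from the normalisation. A 1.5-fold threshold, which admits smaller differences by construction, gave 688 higher and 661 lower genes for PMA in mock cells, 189 and 120 for PMA in siRNA cells, 194 and 364 for siRNA without PMA, 360 and 509 for siRNA with PMA, and 497 and 452 for the difference between arms. A floor at the 75th percentile, which tests fewer genes, gave 36 and 8 for PMA in siRNA cells, 8 higher for siRNA without PMA, 55 higher for siRNA with PMA and 99 lower for the difference between arms. Without a floor, 24 genes were lower with PMA in siRNA cells and 47 higher with siRNA without PMA. The additive PMA term passed for 0 genes without the siRNA term, which leaves siRNA differences in the error, and for 3 genes without a floor or with a trended robust prior. The lower-gene ratio was 0.686 when genes were chosen in the siRNA arm, which favours that arm by construction. Of list medians, 552 stayed and 63 moved, 56 of them with members above the floor only. Of values of list members and named genes, 6830 stayed and 40 of 15 genes moved, all with the mean of probes, among them 4 each of EGR1 and DUSP5 and 2 of VIM. The mean of probes cannot move a gene with 1 probe, and the other settings here renormalised values that were already normalised. Most of the 6830 were thus fixed in advance and do not measure stability. No paired analysis was possible because each group has 1 array. Differences of dim probes are limited by signal over background, which the values do not give.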

Other observations

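Stress-response genes were among the others higher with PMA in mock cells. Of 12 p53 targets, 4 were at least 2-fold higher and 0 lower (median 0.33), with the cytokine gene GDF15 at 11.2-fold, TP53INP1 at 3.85-fold and SESN2, a sestrin, at 3.68-fold. In PKCtheta siRNA cells GDF15 was the 1 member past 2-fold (3.66-fold). Of 13 genes of the ATF4 and endoplasmic reticulum stress list, 3 were higher and 1 lower in mock cells (median 0.31), with the transcription factor DDIT3 at 2.16, DDIT4 at 1.38 and PHGDH, an enzyme of serine synthesis, at −1.05. Of 14 microRNA precursors, MIR21 and MIR221 (below the floor) were higher by 3.17 and 1.75 in mock cells (median 0.28), and MIR21 by 1.55 in PKCtheta siRNA cells. With PMA, MIR21 (−1.25), MIR221 (−1.17) and MIR200C (−1.15) were lower with PKCtheta siRNA than with mock siRNA, and of these MIR21 alone was above the brightness floor. A precursor signal does not give the level of the mature microRNA.

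Of 17 keratinisation and squamous genes, 3 were at least 2-fold higher with PMA in mock cells (median 0.10), KRT80 by 2.16, the calcium-binding S100P by 1.21 and S100A8 by 1.11, and 0 in PKCtheta siRNA cells. Of 16 chromatin genes, the histone demethylase gene KDM6B was higher by 1.31 and the DNA methyltransferase gene DNMT1 differed by −1.21 (median −0.01). Of 12 TGF-beta pathway genes, SMAD3 was 2.74-fold higher (median −0.10). In unstimulated cells, BAMBI, a receptor-like inhibitor of that pathway, differed by −1.29 with PKCtheta siRNA. Of 10 hypoxia and glycolysis genes, VEGFA was 2.15-fold higher with PMA in mock cells (median 0.23, or 0.51 over the 7 above the floor). The 17 cholesterol and lipid synthesis genes had a median of −0.32, at the 0.29th percentile of matched random lists, with 0 members 2-fold apart. Heat shock genes (6, median −0.01), housekeeping genes (7, median −0.07), endothelial markers (7, 2 of them above the floor, median −0.02) and fibroblast markers (3, all below the floor, median 3e-05) had 0 members 2-fold apart with PMA in mock cells. Of 5 leukocyte markers, CD68 was 2.63-fold higher in mock cells and 1.06-fold in PKCtheta siRNA cells.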
